A study of Mus musculus with 8 samples.

How the data were processed

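Gene expression had been measured with 1-colour (Cy3) Agilent 8x60K mouse arrays in 4 sorted populations of CD4+ T cells, 2 arrays per population, 8 in all, on 1 slide scanned in 1 run. Per the labels, cells were sorted from a CD3+CD4+ gate or from a CD4+CD8-CD11c-CD19- gate, and the labels do not say which gate served which sample. The scanner files hold spot intensities that Agilent Feature Extraction 10.7.3.1 had made from the scan, subtracting background and removing spatial trends, per the file headers. The deposited value table holds log2 values, and compared with the scanner files these were shifted to the 75th percentile of each array and centred per probe, to a reference that stays unknown. Of its 55821 values per array, 55681 matched probes of the scanner files. Agreement was measured over probes well above background on both arrays of at least 1 group and with a value on every array. Among these, differences between arrays agreed within 0.01 for 100% (slope 0.99995). The medians of its columns were 0.617 and 0.475 (Foxp3-RORgt- replicates 2 and 3), 0.272 and 0.0592 (Foxp3+RORgt-), -0.0488 and 0.0893 (Foxp3-RORgt+), and -0.185 and -0.00327 (Foxp3+RORgt+).

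The analysis started from the processed spot intensities. Of 62976 spots per array, 3671 control spots were left out, as were spots flagged as outliers by the scanner software (238 to 570 per array). The log2 of the processed signal was taken, the 75th percentile of the array was subtracted, and spots of the same probe were averaged. By the software's own flag, 38.9% and 40.9% of probes were well above background on Foxp3-RORgt- replicates 2 and 3, 41.1% and 45.2% on Foxp3+RORgt-, 44.1% and 43.1% on Foxp3-RORgt+, and 47.2% and 44.5% on Foxp3+RORgt+. The 75th percentiles of the processed signal were, in the same order, 101, 93.5, 115, 133, 177, 151, 190 and 162. No spot was saturated. The files give no gene names, so probes were named through RefSeq accessions in the annotation of GRCm38.p6, whereas the array's own coordinates are mm9, and no coordinate is given here. Of the 55681 probes, 28685 carried a RefSeq accession, 27235 were named and 28446 stayed unnamed, among them 16194 probes for chromosome regions. For 1450 of the probes with an accession no single gene was found. The named probes covered 20660 genes, and probes without a gene name were left out of the main tests, as were 50 probes without a value on some array. Probes well above background on both arrays of at least 1 group were kept, with 1 probe per gene, that with the highest mean, which left 12155 genes.

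Tests used limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8), and figures used matplotlib 3.10.9 in Python 3.11.15. A single model with a coefficient per group was fitted to all 8 arrays (4 residual degrees of freedom, 3.516 prior degrees of freedom from eBayes without trend). The 4 main comparisons were each population with 1 factor against Foxp3-RORgt- cells, and Foxp3+RORgt+ cells against each population with 1 factor. The 2 remaining pairs were compared by counts, and the interaction was the RORgt difference among Foxp3+ cells minus that among Foxp3- cells. Benjamini-Hochberg adjusted p under 0.05 made a call. Distances between arrays were root mean square log2 differences over the tested genes after removal of the median difference. The shared Foxp3 and RORgt effects were correlations across genes of 2 comparisons that have no array in common.

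Gene lists were fixed before the data were examined: 24 lists with 409 entries and 361 distinct genes, of which 347 were named on the array and 301 tested. They covered the Treg signature, genes low in Treg cells, effector Treg, Th17, Th1, Th2, Tfh, naive, activated and memory, migration, proliferation, immediate early and heat shock, interferon response, glycolysis, cholesterol synthesis and T cell identity genes. Others held markers of NKT and gamma-delta T cells, LTi and ILC3 cells, B cells, plasma cells, myeloid and dendritic cells, CD8 T and NK cells, erythroid cells and platelets, and stromal and endothelial cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over 120 tests, and again with an estimated correlation, under which 0 lists were called. Some genes belong to more than 1 list. Foxp3 and Rorc are in none.

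The genes named in the text were chosen by a rule fixed before the data were examined, among called genes with a proper symbol. Besides Foxp3 and Rorc, it took up to 8 genes with the highest and 8 with the lowest difference per main comparison, among genes well above background on at least 1 array of each group. It also took up to 4 per direction with the largest lower bound among genes dim on all arrays of 1 group, up to 5 per direction for the interaction, and 2 to 4 list members with the smallest p. Among these list members, ones whose call held in the alternatives were preferred, a choice made after the values were seen. For a lower bound, each array of the dim group was set to the lowest level at which a probe was well above background there, or to the measured level if that was higher.

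The model was tested on simulated data made for Foxp3+RORgt- against Foxp3-RORgt- cells over the 12155 genes, with 200 changed genes in each of 20 draws. Of changes of 0.5, 1, 2 and 3 log2 units, 0.6%, 26.5%, 93.4% and 98.7% were recovered, with 0 wrong signs and 7.5 false calls per draw. A shift of 1 planted in the Th17 list, for Foxp3-RORgt+ against Foxp3-RORgt- cells, was called in 20 of 20 draws. Tests of the other lists gave 9 calls over these draws. Some of those lists share members with the Th17 list, such as Maf and Ccr6, so these calls do not give a rate of false calls. Genes were simulated independently of each other and without effects of the replicate number. The simulation therefore does not show how the gene or list tests behave where genes or arrays are correlated.

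Alternatives planned beforehand were quantile normalization, scaling to the median, no detection filter, detection on all 8 arrays, all probes, trend and robust eBayes, fits of 2 groups alone, the replicate number as a block, a 2-fold minimum, the deposited value table, and leaving out each array. Normexp (offset 50) had been planned on mean signals, which the files lack, so it was run on the median signal of each spot instead. A fit with the unnamed features was also added after the files were seen.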

Results

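Gene expression was measured in CD4+ T cells taken directly from C57BL/6 mice that carried a red fluorescent reporter for Foxp3 and a green one for RORgt. Foxp3 is the transcription factor that defines regulatory T cells (Treg cells), and RORgt, encoded by Rorc, is the transcription factor of Th17 cells and of type 3 innate lymphoid cells. Cells of spleen, peripheral and mesenteric lymph nodes were pooled and sorted into 4 populations, Foxp3-RORgt-, Foxp3+RORgt-, Foxp3-RORgt+ and Foxp3+RORgt+. Each population was hybridised to 2 arrays, numbered 2 and 3 in the labels, which made 8 arrays of 1 slide. The labels do not say whether the arrays of a population came from separate mice, so the p-values measure only the spread between these arrays, which may be technical. Between 21647 probes (Foxp3-RORgt- replicate 2) and 26261 probes (Foxp3+RORgt+ replicate 2) of 55681 were well above background, and no spot was saturated. The number of arrays limits the precision of every value. The stated purpose was the global relationship between the profiles of the 4 populations. Below, a level is a log2 signal minus the 75th percentile of its array, a difference is a log2 difference between 2 groups of 2 arrays ± its standard error, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 in limma. A gene not well above background on any array of a group has only a lower bound there, given as "at least N-fold".

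Foxp3 and Rorc, on which the cells were sorted, followed the labels on all 8 arrays. Foxp3 lay at 5.85 ± 0.28 (SD, n = 2) in Foxp3+RORgt- and at 6.05 ± 0.19 in Foxp3+RORgt+ cells, against -1.18 ± 0.22 in Foxp3-RORgt- and -1.60 ± 0.12 in Foxp3-RORgt+ cells. Rorc lay at 6.76 ± 0.06 in Foxp3-RORgt+ and at 6.66 ± 0.16 in Foxp3+RORgt+ cells. In the populations sorted as RORgt-, Rorc lay at 0.86 ± 0.25 in Foxp3+RORgt- and at -0.97 ± 0.14 in Foxp3-RORgt- cells. Rorc was thus 3.55-fold higher in Foxp3+RORgt- than in Foxp3-RORgt- cells (limma adjusted p = 0.00155). Neither Foxp3 between the Foxp3+ populations (difference 0.20 ± 0.22) nor Rorc between the RORgt+ populations (difference -0.10 ± 0.20) was called.

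**Figure D1:**
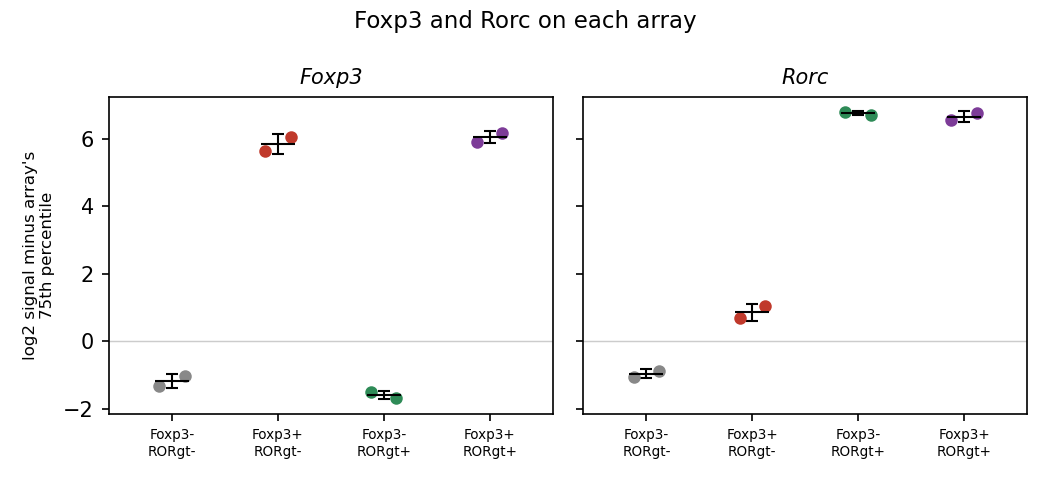
Levels of Foxp3 and Rorc on each of the 8 arrays (points), with the mean and SD of the 2 arrays per group (bars), as log2 signal minus the 75th percentile of the array. Foxp3 lies near 6 only in the 2 Foxp3+ groups, and Rorc near 7 only in the 2 RORgt+ groups, with Rorc at 0.86 in Foxp3+RORgt- and -0.97 in Foxp3-RORgt- cells.

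Across the 12155 genes tested, Foxp3+RORgt+ cells lay closest to Foxp3+RORgt- cells. The root mean square log2 difference between their arrays was 0.780 ± 0.051 (SD over 4 array pairs). It was 0.893 ± 0.058 between Foxp3+RORgt+ and Foxp3-RORgt+ cells, and 1.03 ± 0.051 between Foxp3+RORgt+ and Foxp3-RORgt- cells. The 4 pairs share arrays, so these SDs are not over independent values. Single pairs ranged from 0.714 to 0.825 for Foxp3+RORgt- and from 0.817 to 0.947 for Foxp3-RORgt+ cells, so the 2 ranges overlapped slightly. Foxp3+RORgt- and Foxp3-RORgt- cells differed by 0.818, Foxp3-RORgt+ and Foxp3-RORgt- cells by 1.0, and the populations with 1 factor each by 1.03. The 2 arrays of a population differed by 0.379 to 0.563, less than any pair of arrays from different populations (at least 0.714). Foxp3+RORgt+ against Foxp3-RORgt- cells gave 2340 genes (1368 higher, 972 lower), and Foxp3+RORgt- against Foxp3-RORgt+ cells gave 1835 genes (874 higher, 961 lower). In the former most were lower without the detection filter (1385 higher, 5351 lower) and with unnamed features (1577 and 2024), and in the latter most were higher with unnamed features (1293 and 1024) and with detection on all 8 arrays (748 and 652). The latter split was 884 and 1235 after quantile normalization, 566 and 928 after scaling to the median, and 596 and 574 without Foxp3-RORgt+ replicate 2. Without Foxp3+RORgt+ replicate 2 or 3 the count against Foxp3-RORgt- cells was 1184 and 1280. The count between the populations with 1 factor each was 857 and 1209 without Foxp3+RORgt- replicate 2 or 3, and 1170 without Foxp3-RORgt+ replicate 2. With each array scaled to its median, the split against Foxp3-RORgt- cells was 2893 higher and 407 lower.

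**Figure D2:**
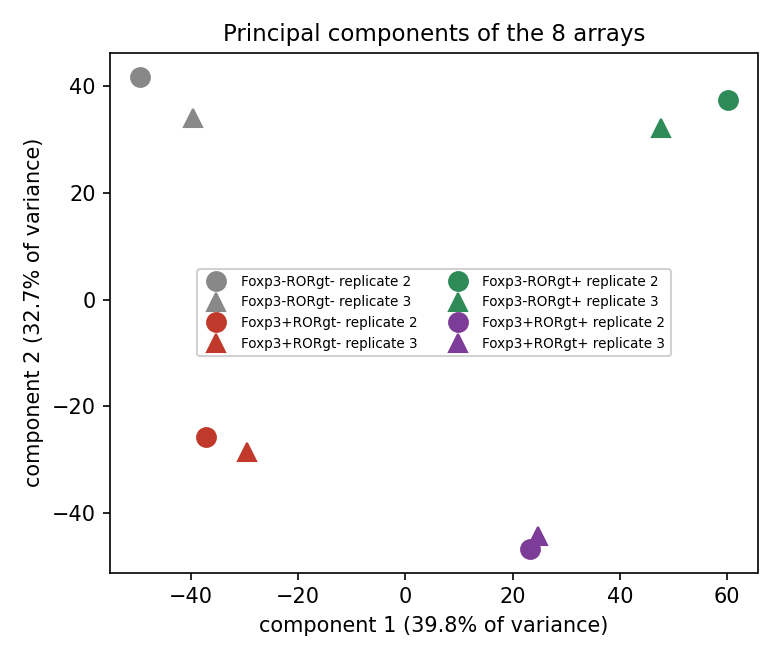
Principal components 1 and 2 of the 12155 tested genes over the 8 arrays, with 39.8% and 32.7% of the variance. Colours mark the 4 groups and symbols the replicate numbers, and the 2 arrays of each group lie side by side, with the 2 RORgt+ groups at positive values of component 1 and the 2 Foxp3+ groups at negative values of component 2.

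The first comparison, Foxp3+RORgt- against Foxp3-RORgt- cells, sets Treg cells against other CD4+ T cells where neither was sorted for RORgt. All 19 measured members of the Treg signature list were higher in Foxp3+RORgt- cells, with a median difference of 3.14, or 2.90 with the 2 members that were dim in Foxp3-RORgt- cells at their bounds. Lrrc32, the surface docking receptor of latent TGF-beta, was 245-fold higher, at 6.10 ± 0.01 against -1.84 ± 0.30. Il2ra, a chain of the interleukin 2 receptor, was 51.8-fold higher, and the transcription factor Ikzf4 differed by 3.90 ± 0.18. Gpr83, an orphan-type receptor, was at least 4.63-fold higher. The list was called higher (adjusted p = 1.26e-29, and adjusted p = 0.294 with an estimated correlation), and all 19 members also passed when adjusted over the list alone.

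Effector Treg genes rose as well in Foxp3+RORgt- cells, with 11 of 19 called higher and none lower (median 1.56, or 1.15 over 18 members with 3 at their bounds). Among them, Klrg1, an inhibitory receptor of differentiated cells, differed by 5.23 ± 0.54, Il1rl1, the receptor of interleukin 33, by 4.57 ± 0.47, and Ebi3, a cytokine subunit, by 3.44 ± 0.28. Klrg1 and Il1rl1 were well above background on 1 of the 2 Foxp3-RORgt- arrays. Other genes with large differences were Hspb1, Sh3bgrl2 and Il1r2, at 5.14 ± 0.54, 5.08 ± 0.50 and 4.46 ± 0.42, each on 1 of 2 Foxp3-RORgt- arrays. Lamc1, Rln3, Matn2 and Fcmr were at least 17.9-fold, 15.5-fold, 14.4-fold and 14.0-fold higher. Adjusted p for the effector Treg list was 4.28e-12, and adjusted p = 0.325 with an estimated correlation. Adjusted over the list alone, 16 members were higher, and at the main threshold 6 were called without Foxp3+RORgt- replicate 2.

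Genes low in Treg cells fell in the same comparison, with 8 of 15 lower and 1 higher (median -1.12). Pde3b, a phosphodiesterase, was 34.7-fold lower, and Dapl1 differed by -3.92 ± 0.29, Themis by -1.99 ± 0.21 and Igfbp4 by -1.91 ± 0.18. Naive T cell genes, a list that shares members with the former, were lower in 7 of 18 and higher in none (median -0.86). Pdlim4 had the largest decrease among genes seen in both groups, from 5.53 ± 0.37 to -1.32 ± 0.07. App, Lypd6b, Nme4, Nacc2, Sytl3 and the cytokine gene Il21 fell by between 4.93 and 4.12, with App and Nacc2 well above background on 1 of 2 Foxp3+RORgt- arrays. Klrd1, a chain of a natural killer cell receptor, was at least 70.3-fold lower, and Atp8b4, Lrrc75b and Amz1 were at least 15.8-fold, 15.3-fold and 13.8-fold lower. The lists low in Treg cells and naive T cell genes were called lower (adjusted p = 9.61e-07 and 7.40e-10), with adjusted p = 0.336 and adjusted p = 0.325 with an estimated correlation. Adjusted over the list alone, 10 members were lower in the former and 11 in the latter. Without 1 array the members called lower fell to as few as 5 in the former and 2 in the latter, and the 1 called higher in the former was not called without Foxp3-RORgt- replicate 2.

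Migration receptors were higher in 5 of 19 and lower in 3 without a call of the list (limma camera adjusted p = 0.950), and without Foxp3+RORgt- replicate 2 the numbers were 3 and 0. Ccr6, the receptor of Ccl20, differed by 4.44 ± 0.20, Gpr15, a gut homing receptor, was at least 6.53-fold higher, and Ccr8 at least 12.8-fold higher in Foxp3+RORgt- cells. Of the Th17 list, 3 of 15 members were higher, among them Ccr6 and Ahr (2.11 ± 0.26), and 3 were lower, among them Il21, and the list was not called by camera in limma (adjusted p = 0.922). Without 1 array these fell to as few as 2 higher and 1 lower. T cell identity genes moved little, with 1 of 13 called (Itk, difference -1.03 ± 0.17, with a limma adjusted p of 0.056 without either Foxp3+RORgt- replicate and 0.108 after scaling to the median) and a median of -0.16. Negative control spots lay at -5.33 in Foxp3+RORgt- and -4.65 in Foxp3-RORgt- cells, so genes at background shift down in this comparison. Such genes enter the test of the next list. Markers of NKT and gamma-delta T cells were lower (2 of 8, median -0.84, or -2.84 over the 3 members not dim in both groups, adjusted p = 0.000148, and adjusted p = 0.336 with an estimated correlation), led by Zbtb16, a transcription factor of innate-like T cells, which was at least 9.62-fold lower. Only 1 was called without either Foxp3+RORgt- replicate. In all, 946 genes were called, 659 higher and 287 lower. The count was 423 without Foxp3+RORgt- replicate 2 and 468 without replicate 3. With each array scaled to its median, 1167 genes were higher and 187 lower, since the median of all genes then moved to 0.36.

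The comparison of Foxp3-RORgt+ with Foxp3-RORgt- cells asks what goes with RORgt in cells without Foxp3. Th17 genes rose in 14 of 15 measured members, with a median difference of 6.05, or 4.01 with the 5 members that were dim in Foxp3-RORgt- cells at their bounds. Ccr6 was 247-fold higher, and Tmem176b, a membrane protein gene, differed by 6.24 ± 0.29. The cytokine gene Il17a was at least 44.2-fold higher, and Il17re, which encodes the receptor of interleukin 17C, at least 86.3-fold. The list was called higher (adjusted p = 2.93e-15, and adjusted p = 0.294 with an estimated correlation), with the same 14 members adjusted over the list alone. Lingo4, a gene outside the lists, was at least 336-fold higher. Serpinb1a, a serine protease inhibitor, differed by 8.22 ± 0.68, Tmem176a by 6.71 ± 0.43, Cpe by 6.56 ± 0.32 and Cited4 by 5.81 ± 0.37, each with 1 of 2 Foxp3-RORgt- arrays well above background.

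Foxp3-RORgt+ cells had higher levels of genes of activated and memory T cells, with 17 of 24 called higher and 1 lower (median 1.30). Cd44, an adhesion receptor of antigen-experienced T cells, differed by 1.82 ± 0.20, S100a11 by 1.86 ± 0.19 and Ahnak by 2.43 ± 0.26, while Ccl5 differed by -3.51 ± 0.40. Migration receptors were higher in 10 of 19 and lower in 4 (median 1.12), with Ccr4 at a difference of 4.27 ± 0.27 and Gpr15 at least 21.9-fold higher. Proliferation genes were higher in 8 of 27 and lower in none (median 0.75), among them Top2a (1.94 ± 0.19) and Prc1 (1.56 ± 0.20). Effector Treg genes rose in 10 of 19, among them Maf (2.67 ± 0.20) and Irf4 (2.33 ± 0.18), both transcription factors of activated T cells. Of the Treg signature, 9 of 19 rose and 1 fell, with Il2ra at 4.31 ± 0.26, Socs2 at 2.91 ± 0.27 and Ctla4 at 2.66 ± 0.27. With dim members at their bounds the medians of the last 3 lists were 0.65, 1.18 and 0.79. These 5 lists were called higher by camera in limma, with adjusted p = 3.55e-06, 0.00275, 7.68e-05, 5.24e-07 and 0.00269. In the same order the values were adjusted p = 0.444, 0.444, 0.641, 0.348 and 0.609 with an estimated correlation. Adjusted over the list alone, 18, 11, 15, 13 and 9 members were higher. At the main threshold and without 1 array the lowest numbers called higher were 14, 7, 5, 8 and 6, with as few as 2 migration receptors and no Treg signature gene lower.

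Naive T cell genes were lower in 10 of 18 and higher in 1 (median -0.72, adjusted p = 1.62e-05, and adjusted p = 0.336 with an estimated correlation). Without Foxp3-RORgt+ replicate 2 only 6 were lower. Dapl1 was 72.3-fold lower, and Igfbp4 and the transcription factor Bach2 differed by -3.73 ± 0.18 and -2.19 ± 0.23. Ccr9, a gut homing receptor of the same list, was higher by 2.54 ± 0.30. Sostdc1 and Ascl2, members of the Tfh list, differed by -4.67 ± 0.18 and -3.25 ± 0.21, although that list was not called by camera in limma (adjusted p = 0.800). Stfa3 and Snora74a were 31.6-fold and 21.2-fold lower. Eomes, a transcription factor of cytotoxic cells, differed by -4.28 ± 0.40 (Stfa3 and Eomes on 1 of 2 Foxp3-RORgt+ arrays), and the chemokine gene Ccl4 was at least 10.2-fold lower. Piezo2, Rhox3a and Flg2 were at least 10.3-fold, 9.79-fold and 9.26-fold lower, with Piezo2 at a limma adjusted p of 0.054 in a fit of the 2 groups alone. These bounds hold for group means. Piezo2 and Rhox3a varied widely between the Foxp3-RORgt- arrays (SD 2.24 and 1.52), so the fold against a single array can be smaller. The calls of Rabgap1 and Tdgf1, at -3.84 ± 0.79 and -3.62 ± 0.74, ended without Foxp3-RORgt- replicate 2 in limma (adjusted p = 0.055 and 0.052) and without Foxp3-RORgt+ replicate 3 (adjusted p = 0.061 and 0.055).

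Markers of other RORgt-expressing and innate-like cells were high in Foxp3-RORgt+ cells. Of the LTi and ILC3 list, 8 of 11 members were higher and none lower (median 1.32, adjusted p = 1.68e-05, and adjusted p = 0.367 with an estimated correlation), with 5 higher without Foxp3-RORgt- replicate 2. Kit, the stem cell factor receptor, lay at 3.04 ± 1.03 against -3.50 ± 1.73 (1 of 2 arrays well above background), Fcer1g, an Fc receptor adaptor, differed by 4.75 ± 0.66, and Ncr1, a natural cytotoxicity receptor, was at least 3.48-fold higher. Of the NKT and gamma-delta T cell list, 5 of 8 were higher (median 2.68, or 1.15 with 5 members at their bounds). Klrb1b, a lectin-like receptor, was at least 53.3-fold higher, Cd163l1, a scavenger receptor of gamma-delta T cells, at least 11.4-fold, and the related gene 5830411N06Rik at least 21.3-fold. That list had adjusted p = 0.00139, and adjusted p = 0.368 with an estimated correlation. Among members detected on all 8 arrays its median was -0.43 and its call was lost (camera adjusted p = 0.419). That setting leaves out members dim in Foxp3-RORgt- cells, Klrb1b, Cd163l1 and 5830411N06Rik among them, so it says nothing about these. Cntn1, an adhesion molecule outside the lists, was at least 53.4-fold higher. The MHC class II genes H2-Aa, H2-Eb1 and Cd74, listed among the B cell markers, differed by 4.46 ± 0.54, 3.41 ± 0.42 and 3.64 ± 0.44, while the B cell list as a whole was not called by camera in limma (6 of 11 higher, 2 lower, adjusted p = 0.174). Of the T cell identity genes, 1 of 13 was higher and 1 lower, with a list median of -0.11. Cd3d, a chain of the T cell receptor complex, differed by -1.02 ± 0.21, with a limma adjusted p of 0.20 after quantile normalization and 0.144 after scaling to the median, and of 0.058 without Foxp3-RORgt- replicate 3 and 0.092 without Foxp3-RORgt+ replicate 2.

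In this comparison 2265 genes were called, 1389 higher and 876 lower. Most called genes were lower, however, without the detection filter (1182 higher, 2758 lower) and with unnamed features (1553 and 1903). The count was 1451 without Foxp3-RORgt- replicate 2, 1074 without Foxp3-RORgt+ replicate 2, 1088 in a fit of these 2 groups alone and 4219 with normexp background correction. Scaling to the median gave 3126 higher and 316 lower genes, with the median of all genes at 0.49.

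**Figure D3:**
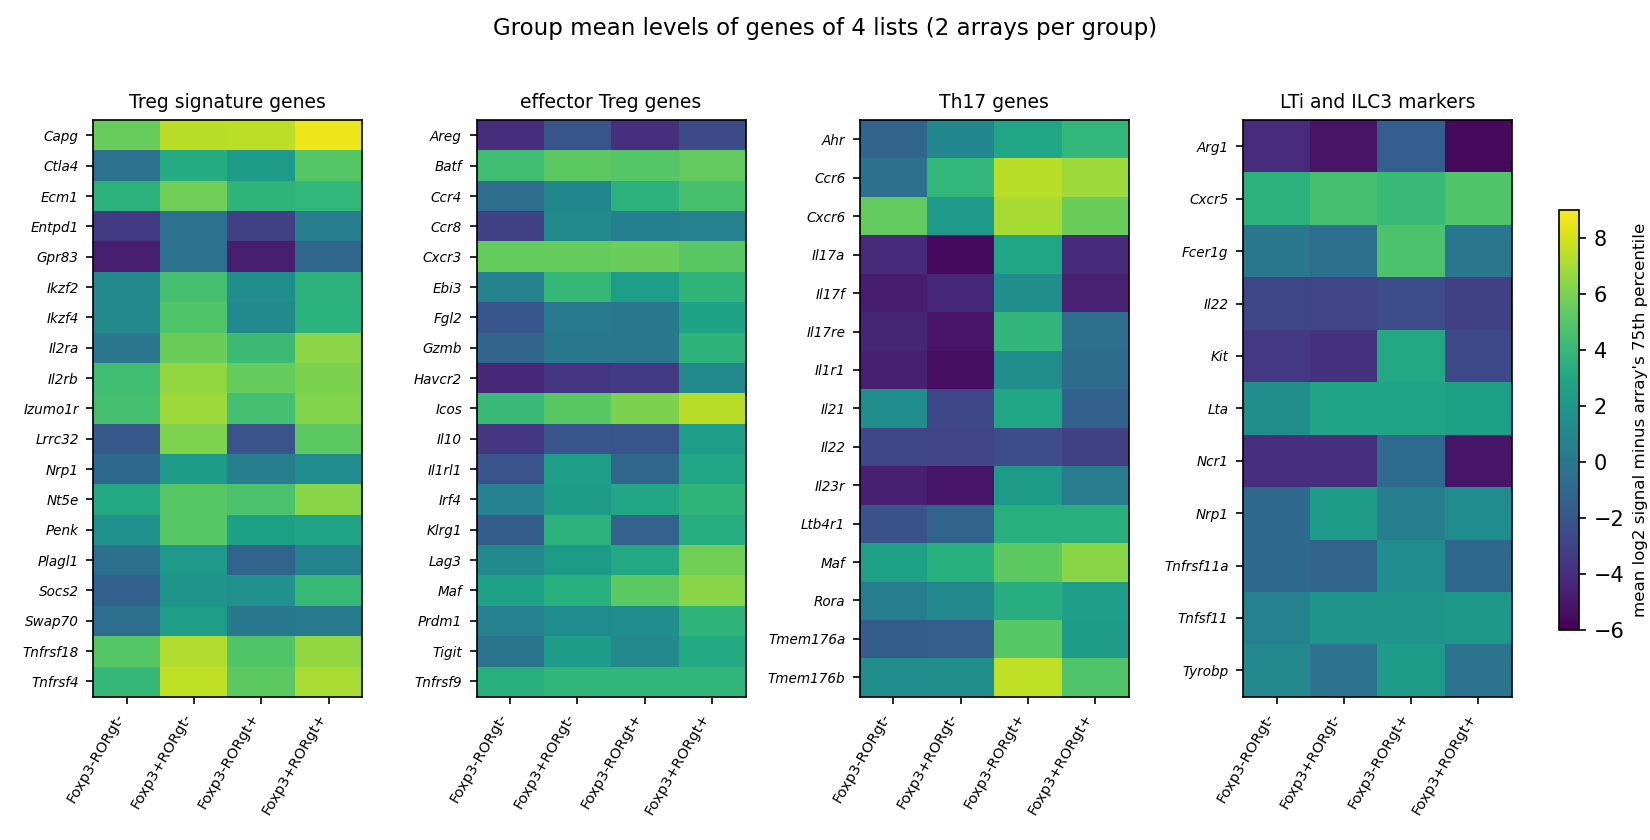
Mean level over the 2 arrays of each group (colour, log2 signal minus the 75th percentile of the array) for the measured genes (rows) of 4 lists in the 4 groups (columns). Treg signature genes are high in both Foxp3+ groups, Th17 genes such as Ccr6 are high in both RORgt+ groups, and Kit (mean 3.04) and Fcer1g stand out in Foxp3-RORgt+ cells.

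Within Foxp3+ cells, the comparison of Foxp3+RORgt+ with Foxp3+RORgt- cells asks what goes with RORgt in Treg cells. Th17 genes rose in 13 of 15 measured members and fell in none (median 2.98, also with 3 members at their bounds). The interleukin 23 receptor gene Il23r was at least 15.3-fold higher and Il17re at least 8.31-fold. Maf differed by 2.83 ± 0.20 and Ccr6 by 2.89 ± 0.20. The list was called higher (adjusted p = 2.79e-15, and adjusted p = 0.294 with an estimated correlation), with 13 members higher adjusted over the list alone and 9 at the main threshold without Foxp3+RORgt- replicate 2. Lingo4 was 119-fold higher, with 1 of 2 Foxp3+RORgt- arrays well above background. Gbp2b, an interferon-inducible GTPase, was 111-fold higher, and Fam20a, Emp1 and Cited4 differed by 6.17 ± 0.29, 6.69 ± 0.49 and 6.05 ± 0.37 (Emp1 and Cited4 on 1 of 2 Foxp3+RORgt- arrays). Serpinb1a differed by 5.28 ± 0.68, with an adjusted p of 0.062 without Foxp3+RORgt- replicate 2. Tph1, the first enzyme of serotonin synthesis outside neurons, was at least 93.5-fold higher, and Plekhf1, C2cd4d and Stom at least 31.2-fold, 26.1-fold and 24.7-fold.

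Effector Treg genes were higher still in Foxp3+RORgt+ cells, with 9 of 19 called higher and none lower against Foxp3+RORgt- cells (median 1.59). Il10, an anti-inflammatory cytokine, was 21.1-fold higher and Lag3, an inhibitory receptor, differed by 3.52 ± 0.21. Havcr2, another inhibitory receptor, was at least 24.2-fold higher. Activated and memory genes rose in 11 of 24 and fell in 2, with Ccr2, a chemokine receptor, 45.0-fold higher, Prdm1 at 2.44 ± 0.23 and Icos at 2.31 ± 0.25. Migration receptors rose in 9 of 19 and fell in 2, with Ccr4 at 3.61 ± 0.27 and Ccr9 at 2.90 ± 0.30 (list median 0.35, or 0.73 over the 18 members not dim in both groups). Proliferation genes rose in 5 of 27 (median 0.76, or 0.59 with 1 member at its bound), but in 0 without either Foxp3+RORgt+ replicate, and in 1 and 2 without Foxp3+RORgt- replicate 2 and 3. The 4 lists were called higher (adjusted p = 7.94e-09, 0.00122, 0.000564 and 4.64e-06), with adjusted p = 0.336, 0.641, 0.368 and 0.584 with an estimated correlation. Adjusted over the list alone, 11, 13, 9 and 10 members were higher. Without Foxp3+RORgt- replicate 2 the activated and memory genes called were 6 higher and 1 lower, and the migration receptors 7 and 0.

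Of the Treg signature, 6 of 19 genes were lower and 4 higher in Foxp3+RORgt+ than in Foxp3+RORgt- cells. Penk, which encodes an opioid peptide precursor, differed by -2.37 ± 0.24, Plagl1 by -1.41 ± 0.17 and Ikzf4 by -1.37 ± 0.18, while Socs2 was higher by 2.23 ± 0.27. The list's lower call (median -0.63, adjusted p = 0.0258, and adjusted p = 0.755 with an estimated correlation) ended without Foxp3+RORgt- replicate 3 (adjusted p = 0.107 by camera), with normexp (adjusted p = 0.0567) and without the detection filter (adjusted p = 0.182). Naive T cell genes fell in 8 of 18 and rose in 1 (median -0.89, adjusted p = 1.68e-05, and adjusted p = 0.336 with an estimated correlation), among them Igfbp4 (-3.20 ± 0.18) and Dapl1 (-3.52 ± 0.29). Leaving out 1 array cut the members called lower to as few as 3 in the Treg signature and 4 in the naive T cell list, and the Treg signature members called higher to as few as 1. The genes low in Treg cells were also lower (6 of 15, adjusted p = 0.00317, and adjusted p = 0.542 with an estimated correlation), with Id3 at -2.03 ± 0.23 and Themis at -1.64 ± 0.21, and 4 were lower without Foxp3+RORgt- replicate 2. Sorcs2, Dnah7a, Nr4a2 and Chadl fell by 3.75, 3.69, 3.67 and 3.43, Nr4a2 on 1 of 2 Foxp3+RORgt+ arrays. Gsta4, Ecel1 and Sostdc1 were at least 22.6-fold, 21.4-fold and 20.7-fold lower. Limma calls of Lad1 (-4.06 ± 0.50) and Ccl1 (-3.94 ± 0.68), each on 1 of 2 Foxp3+RORgt+ arrays, and Slc22a2 (-3.90 ± 0.57) ended without Foxp3+RORgt- replicate 2 (adjusted p = 0.051, 0.100 and 0.085), and those of Ccl1 and Slc22a2 also without replicate 3 (adjusted p = 0.103 and 0.056).

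In contrast to the comparison without Foxp3, 0 of 11 LTi and ILC3 markers were called between Foxp3+RORgt+ and Foxp3+RORgt- cells by limma (median 0.10, adjusted p = 0.816), and Kit lay at -2.68 ± 0.09 in Foxp3+RORgt+ cells. The test of that difference between comparisons is the interaction given further on. NKT and gamma-delta T cell markers rose in 2 of 8, with the list not called by camera in limma (adjusted p = 0.412). One of them, 5830411N06Rik, was at least 4.47-fold higher. Altogether 817 genes were called, 456 higher and 361 lower. The count was 295 and 411 without Foxp3+RORgt- replicate 2 and 3, and 365 and 418 without Foxp3+RORgt+ replicate 2 and 3. Scaling to the median gave 492 higher and 247 lower genes, and detection on all 8 arrays 300 and 320.

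Within RORgt+ cells, the comparison of Foxp3+RORgt+ with Foxp3-RORgt+ cells asks what goes with Foxp3. The Treg signature rose in 14 of 19 genes and fell in none (median 1.87). Lrrc32 was 166-fold higher, Ikzf4 differed by 2.46 ± 0.18 and Entpd1, an ectonucleotidase, by 3.56 ± 0.33. Gpr83 was at least 6.39-fold higher. Effector Treg genes rose in 12 of 19 and fell in none (median 1.47), with Il10 at 4.45 ± 0.25, Gzmb, a cytotoxic granule protease, at 3.69 ± 0.30, Lag3 at 2.75 ± 0.21 and Havcr2 at 4.54 ± 0.35 (1 of 2 Foxp3-RORgt+ arrays). Both lists were called higher (adjusted p = 3.70e-17 and 1.37e-12), with adjusted p = 0.325 and adjusted p = 0.325 with an estimated correlation, and with 16 and 15 members adjusted over the list alone. Without 1 array at least 13 and 8 were still called higher. Klrg1, Fcmr, Hspb1 and Atp6v0d2 differed by 4.60 ± 0.54, 4.53 ± 0.51, 4.52 ± 0.54 and 4.42 ± 0.46, Fcmr and Atp6v0d2 on 1 of 2 Foxp3-RORgt+ arrays. Gbp2b and Tph1 were at least 230.2-fold and 100.3-fold higher. Cyp26b1, a retinoic acid degrading enzyme, was at least 84.2-fold higher, and the matrix protease Mmp9 at least 19.6-fold.

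Th17 genes were lower in Foxp3+RORgt+ than in Foxp3-RORgt+ cells in 7 of 15 members and higher in 2 (median -1.78, adjusted p = 3.30e-07, and adjusted p = 0.325 with an estimated correlation). Il17a was at least 102.7-fold lower and Il17f at least 37.4-fold, neither being well above background in Foxp3+RORgt+ cells. Il21 differed by -4.25 ± 0.25 and Il17re by -4.37 ± 0.28. Adjusted over the list alone, 11 members were lower. Without Foxp3-RORgt+ replicate 2, 6 were lower and none higher at the main threshold. Among Th1 genes 3 of 14 were lower and 1 higher (adjusted p = 0.00148, and adjusted p = 0.609 with an estimated correlation), with the cytokine gene Ifng at -3.21 ± 0.35. The growth factor gene Il2 was at least 28.2-fold lower, Pde3b differed by -3.50 ± 0.18 and Themis by -3.00 ± 0.21. They belong to the genes low in Treg cells, of which 7 of 15 fell, or 5 without Foxp3-RORgt+ replicate 3 (adjusted p = 2.02e-05, and adjusted p = 0.367 with an estimated correlation). Naive T cell genes fell in 9 of 18 and rose in 1 (adjusted p = 0.000241, and adjusted p = 0.367 with an estimated correlation), with Sox4 at least 13.3-fold lower, and as few as 3 fell and none rose without 1 array.

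Innate-like markers were lower in Foxp3+RORgt+ cells. NKT and gamma-delta T cell markers fell in 7 of 8 (median -3.91, or -3.25 with 4 members at their bounds), with Klrb1b at least 123.8-fold and Cd163l1 at least 26.4-fold lower and Zbtb16 at -4.57 ± 0.44 (1 of 2 Foxp3+RORgt+ arrays). LTi and ILC3 markers fell in 6 of 11 and rose in 1 (median -2.26), or 5 and 0 without Foxp3+RORgt- replicate 2, with Kit at -5.72 ± 0.86, Fcer1g at -4.86 ± 0.66 and Arg1 at least 4.82-fold lower. The lists were called lower (adjusted p = 7.36e-10 and 0.00276), with adjusted p = 0.325 and adjusted p = 0.542 with an estimated correlation. Among members detected on all 8 arrays neither list was called by camera in limma (adjusted p = 0.0605 and 0.240). Klrb1b, Cd163l1 and Arg1, dim in Foxp3+RORgt+ cells, are not among those members. H2-Aa and H2-Eb1 differed by -5.54 ± 0.54 and -4.11 ± 0.42. Outside the lists, Cntn1 fell by 6.74, and Upp1, Qpct, Plcg2, Car2 and Tns3 were 65.5-fold, 48.2-fold, 47.1-fold, 42.9-fold and 36.9-fold lower, all but Qpct and Plcg2 on 1 of 2 Foxp3+RORgt+ arrays, and Cx3cl1 and P2ry1 were at least 65.3-fold and 44.3-fold lower. Without the detection filter the probe with the highest mean is chosen among all probes of a gene, dim ones included. Tns3 was then not called by limma (adjusted p = 0.795), so its fold holds only for the probe of the main test. T cell identity genes had a median of -0.06, and Itk alone of 13 was called (-0.94 ± 0.17), with a limma adjusted p of 0.066 and 0.064 without Foxp3-RORgt+ replicate 2 and 3, and 0.129 and 0.052 without Foxp3+RORgt+ replicate 2 and 3. In total 1142 genes were called, 570 higher and 572 lower. The count was 505 without Foxp3+RORgt+ replicate 2 (238 higher, 267 lower), 619 without replicate 3 (241 and 378), and 1794 with normexp (1065 and 729). With detection on all 8 arrays it was 477 and 356, so the split depends on the setting.

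**Figure D4:**
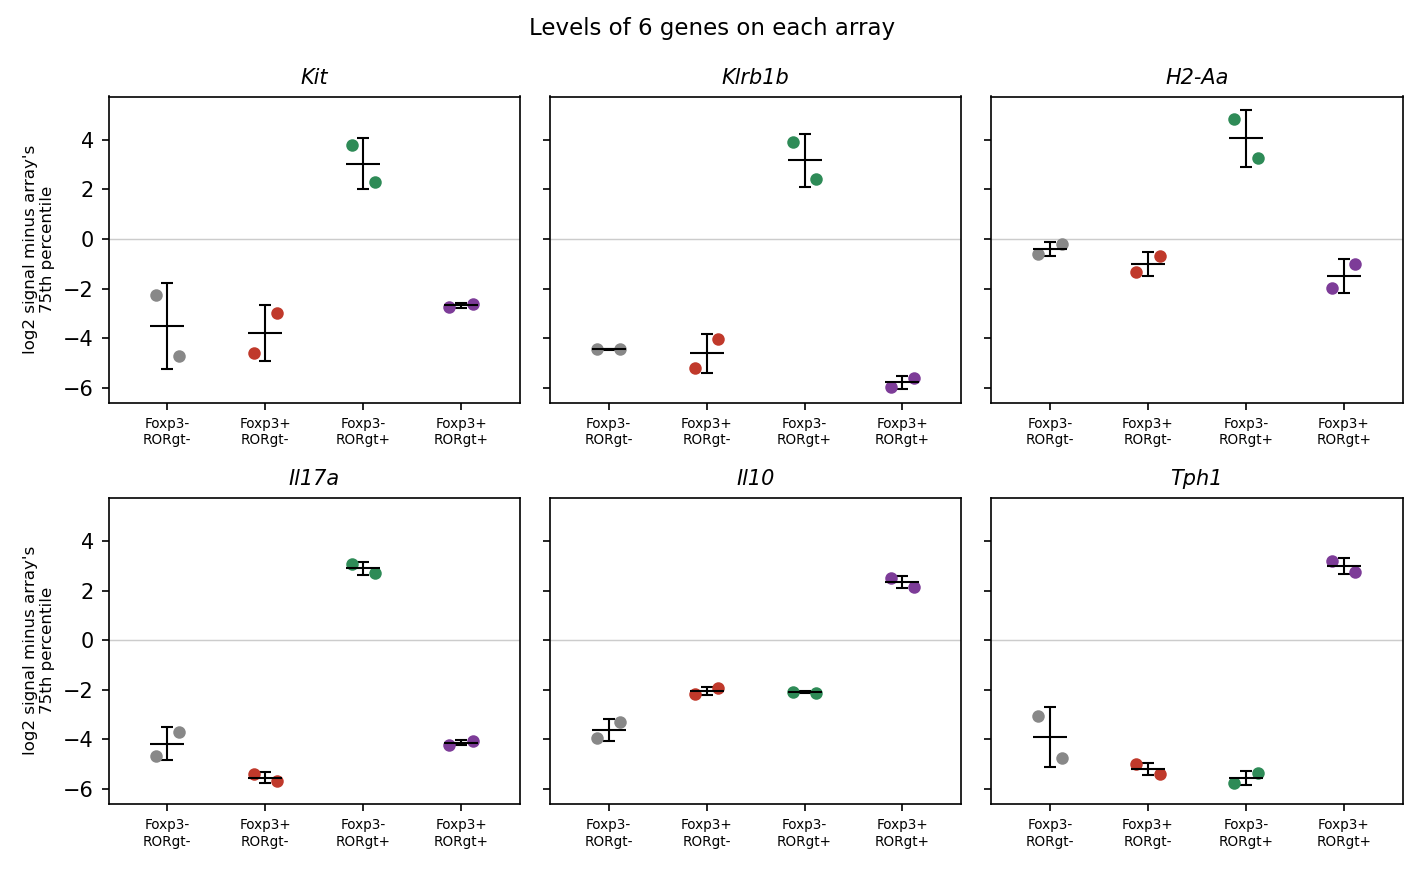
Levels of Kit, Klrb1b, H2-Aa, Il17a, Il10 and Tph1 on each array (points), with the mean and SD of the 2 arrays per group, as log2 signal minus the 75th percentile of the array. Kit, Klrb1b, H2-Aa and Il17a are high in Foxp3-RORgt+ cells (Kit at 3.04 ± 1.03), and Il10 and Tph1 in Foxp3+RORgt+ cells (Tph1 at 2.99 ± 0.31).

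The differences that went with Foxp3 were partly alike with and without RORgt. Across genes, which are not independent replicates, the differences of the 2 Foxp3 comparisons, which share no array, had a Pearson correlation of 0.424 (Spearman 0.323). Of the genes called, 236 were higher in both comparisons where independent lists would share 30.9, and 157 were lower in both where they would share 13.5. Lrrc32, Klrg1 and Gpr83 were among those higher in both, and Pde3b and Il21 among those lower in both. Called genes with opposite directions numbered 17 and 6. The differences that went with RORgt had a correlation of 0.496 (Spearman 0.503) between cells with and without Foxp3. Of them, 306 genes were higher in both where 52.1 would be shared and 176 lower in both where 26.0 would be shared, with 19 and 10 in opposite directions. Ccr6, Lingo4, Il23r, Maf and Cited4 were among those higher in both, and Dapl1, Igfbp4 and Sostdc1 among those lower in both.

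**Figure D5:**
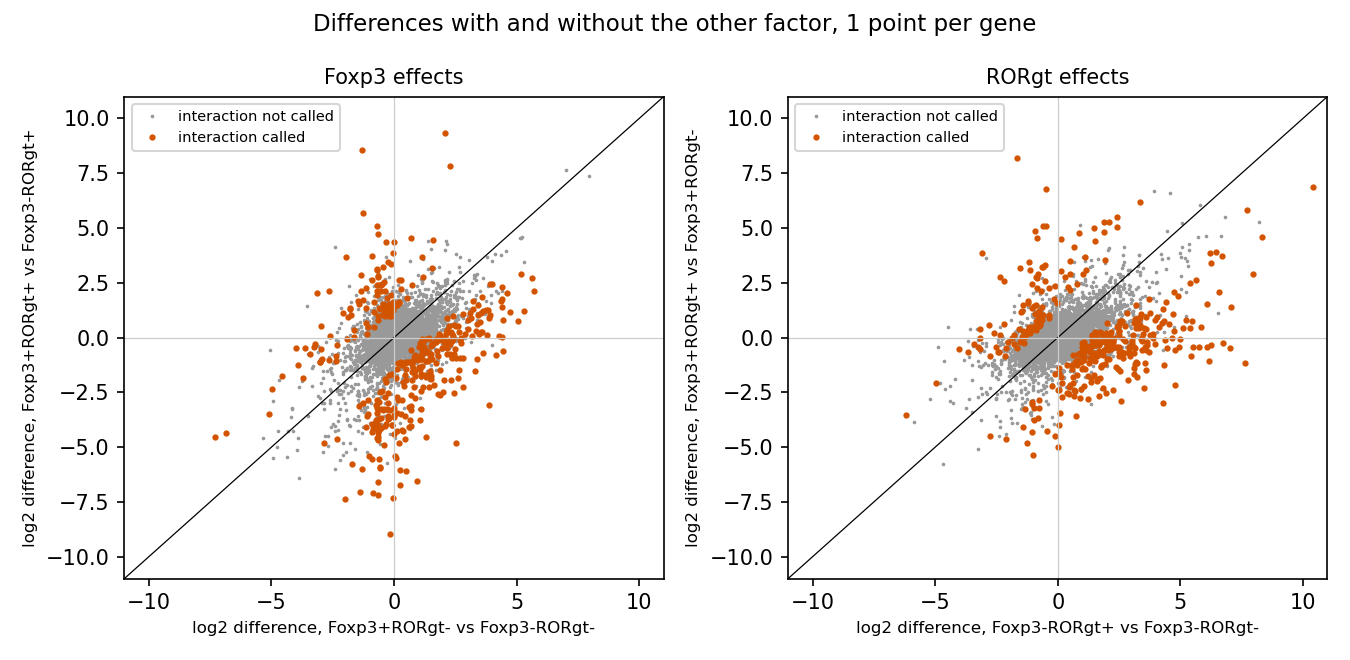
Log2 difference of each tested gene in 2 comparisons, for Foxp3 (left: without RORgt on the x axis, with RORgt on the y axis) and RORgt (right: without Foxp3 on the x axis, with Foxp3 on the y axis), with the line of equal differences. Orange points are the 381 genes with a called interaction, most of which (270) lie below the line.

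The interaction, which tests whether the RORgt difference was unlike in cells with and without Foxp3 (equally, the Foxp3 difference with and without RORgt), was called for 381 genes, 111 higher and 270 lower. Th17 genes had a smaller RORgt difference in Foxp3+ cells, with 6 of 15 lower and none higher (median -1.41, adjusted p = 2.13e-07, and adjusted p = 0.325 with an estimated correlation). Among them was Ccr6 (-5.06 ± 0.28), which was high in 3 of the 4 populations, at 7.42 ± 0.31 in Foxp3-RORgt+ cells. Il17f and Il17a were called too, but were well above background in Foxp3-RORgt+ cells alone, so their interaction has no measured size. Treg signature genes were lower in 7 of 19 (median -0.88, adjusted p = 4.90e-10, and adjusted p = 0.336 with an estimated correlation), among them Il2ra (-3.58 ± 0.36) and Penk (-3.30 ± 0.33). LTi and ILC3 markers were lower in 2 of 11 (median -2.07, adjusted p = 5.24e-07, and adjusted p = 0.336 with an estimated correlation) and NKT and gamma-delta T cell markers in 3 of 8 (median -1.96, adjusted p = 7.68e-05, and adjusted p = 0.336 with an estimated correlation). The medians of the 4 lists include members at background in some groups. Among members detected on all 8 arrays the last was -0.16. There the call of the NKT and gamma-delta list was lost (camera adjusted p = 0.997) and the direction given by camera turned. Members dim in a group, such as Klrb1b, are left out in that setting, so it does not test their interaction. Without Foxp3+RORgt- replicate 2 or 3, the called members were 5 and 4 for Th17 genes, 2 and 2 for the Treg signature, 0 and 0 for LTi and ILC3 markers, and 1 and 1 for NKT and gamma-delta markers. Adjusted over the list alone, 9 Th17, 11 Treg signature, 8 LTi and ILC3, and 5 NKT and gamma-delta members were lower. Calls that held without any 1 array included, as higher, Tph1 and Hacd4, well above background in Foxp3+RORgt+ cells alone, and Gbp2b, seen in both Foxp3+ groups, and as lower Klrb1b and Cx3cl1, seen in Foxp3-RORgt+ cells alone. Because the other groups lay at background, the fitted values of these genes are not read as sizes. The count was 63 and 75 without Foxp3+RORgt- replicate 2 and 3, 153 and 247 without Foxp3+RORgt+ replicate 2 and 3, and 196 among genes detected on all 8 arrays. Scaling to the median gave 85 higher and 487 lower genes.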

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

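The test of negative control spots and the first test of mast cell markers were chosen before their results were seen, and the tests of B cells, macrophages, innate lymphoid cells and the second test of mast cells after.

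A difference between groups drew attention here: the interaction, in which the RORgt difference with Foxp3 departs from that without it, was called for 381 genes. Fitted values were 9.84 for Tph1, 7.27 for Gbp2b, 6.94 for Mmp9, 5.77 for Hacd4, 5.65 for Plac8, -8.78 for Klrb1b, -7.49 for Cx3cl1, -7.31 for Dscam, -7.24 for Mapk10 and -6.98 for Cntn1. All but Plac8 were above background on no array of at least 1 group, so these values depend on background, are not bounds, and give no order. Without Foxp3+RORgt- replicate 2 or 3 the limma adjusted p was 0.079 and 0.058 for Mmp9, 0.065 and 0.053 for Plac8, 0.128 and 0.091 for Dscam, and 0.079 and 0.053 for Mapk10. For Dscam it was also 0.063 without Foxp3+RORgt+ replicate 2 and 0.052 after quantile normalization, and for Cntn1 0.052 without Foxp3+RORgt- replicate 3. Without the detection filter it was 0.051 for Cntn1, 0.070 for Dscam and 0.052 for Mapk10.

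The same kind of difference between groups was called for 7 lists by camera in limma, though for none with an estimated correlation. Their medians were -0.88 (Treg signature), -1.41 (Th17), -0.42 (activated and memory), -1.96 (NKT and gamma-delta T cells), -2.07 (LTi and ILC3), -0.82 (B cells) and 0.87 (myeloid and dendritic cells). Negative control spots lay at -4.65 in Foxp3-RORgt-, -5.33 in Foxp3+RORgt-, -5.58 in Foxp3-RORgt+ and -5.77 in Foxp3+RORgt+ cells. Background by itself thus gives a positive interaction, which may add to the myeloid median. For the activated and memory list, adjusted p = 0.0464, and adjusted p = 0.755 with an estimated correlation (2 of 24 higher, 2 lower, and 2 and 6 adjusted over the list alone). It was 0.123 after scaling to the median, 0.263 without Foxp3-RORgt- replicate 2, 0.241 without Foxp3+RORgt- replicate 3, 0.101 and 0.0556 without Foxp3-RORgt+ replicates 2 and 3, and 0.114 without Foxp3+RORgt+ replicate 2, and without 1 array the members called fell to as few as 0 in either direction. For the B cell list, adjusted p = 0.00679, and adjusted p = 0.367 with an estimated correlation (4 of 11 lower, and 1 higher and 6 lower adjusted over the list alone), and it was 0.0771 without Foxp3+RORgt- replicate 3. No member was called without either Foxp3+RORgt- replicate or without Foxp3+RORgt+ replicate 2. For the myeloid list, adjusted p = 0.0245, and adjusted p = 0.755 with an estimated correlation (0 of 16 called, and 1 higher and 1 lower adjusted over the list alone). That value was 0.0654 with normexp, 0.149 among members detected on all 8 arrays, 0.0712 without Foxp3-RORgt- replicate 2, 0.0904 without Foxp3+RORgt- replicate 2, 0.0712 without Foxp3-RORgt+ replicate 3 and 0.216 without Foxp3+RORgt+ replicate 3.

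Calls were also made among features that the main tests do not use. Of 7085 features without a gene name, 202 were called in Foxp3+RORgt- against Foxp3-RORgt- cells (105 higher, 97 lower), 1376 in Foxp3-RORgt+ against Foxp3-RORgt- cells (266 higher, 1110 lower), 240 in Foxp3+RORgt+ against Foxp3+RORgt- cells (80 higher, 160 lower) and 244 in Foxp3+RORgt+ against Foxp3-RORgt+ cells (162 higher, 82 lower). Over all 19242 features of that fit the calls numbered 981, 3456, 887 and 1156 in the same order. Negative control spots lay at -5.58 in Foxp3-RORgt+ and -4.65 in Foxp3-RORgt- cells, so background may add to the lower calls there. Whether it does was not tested.

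Innate lymphoid and MHC class II genes were high in Foxp3-RORgt+ cells, where the 4 MHC class II genes, all also detected in Foxp3-RORgt- cells, had a median difference of 3.53. The values argue against B cells and macrophages as the source of the MHC class II difference. Either gate would remove B cells, and a CD3 gate would remove macrophages. B cell genes outside MHC class II had a median difference of -0.61 (upper quartile 0.47, below the lowest MHC class II difference of 2.84). Over the 9 seen above background on some array of the 2 groups, a set chosen after the values were seen, it was -0.72 (upper quartile 0.91). Negative control spots lay at -5.58 in Foxp3-RORgt+ and -4.65 in Foxp3-RORgt- cells, so genes at background fall with or without B cells. Seen in both groups, Cd22, Blnk, Bank1 and Ly6d differed by -1.07, -1.50, -0.83 and -1.69, and Cd79b and Cr2 by 2.17 and 0.33. Fcer2a, dim in Foxp3-RORgt- cells, was higher by 1.09. Abundant macrophage genes had a median difference of -0.46, with Lyz2 at -0.60 and C1qb at -0.14, although Fcgr3 and C1qa were higher by 0.90 and 0.10. CD4+ innate lymphoid cells, which a CD3 gate would remove and the other gate would not, may have been sorted in different shares on the 2 arrays: the LTi and ILC3 list, of whose 11 members 6 are also in other lists, differed by a median of 0.82 between replicates 2 and 3, beyond 0.30, the upper bound of matched random lists, with Kit at 3.78 and 2.31 and H2-Aa at 4.86 and 3.26. The Th17 list (0.35, bound 0.24) and proliferation genes (0.45, bound 0.17) also differed, so different shares of such cells and a general difference between the 2 arrays cannot be told apart. Expression of these genes by RORgt+ T cells themselves stays open and was not tested.

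Genes with a positive interaction numbered 111, and 102 of them were well above background on both Foxp3+RORgt+ arrays (median level -0.51). Mast cells, which a CD3 gate would remove, could bring such transcripts, and a share of 0.333 of 9 mast cell markers (Hdc, Tpsb2 and Kit, all also detected in Foxp3-RORgt+ cells) was well above background on both arrays, between the bounds set beforehand. The second test, added after that outcome was seen, argues against mast cells that carry their protease and Fc receptor transcripts only as far as the probes respond: 0 of 6 such genes were above background on any Foxp3+RORgt+ array (Cpa3 at -5.65), though they were above background on no array of the other groups either, so no array here shows that these probes respond. For macrophages, a share of 0.889 of 9 abundant genes was well above background there, against 0.778 in Foxp3-RORgt+ cells, with C1qa and C1qc higher than in Foxp3+RORgt- cells by 1.83 and 1.56 but Csf1r and Cybb at -0.66 and -1.06 and a median difference of 0.28, which lies between the bounds and leaves them open. No biological explanation was tested.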

How the results depend on the processing

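Normexp on median signals and the test with unnamed features were chosen after the files were seen, and the planned normexp on mean signals was not run because the files lack them. Over all alternatives, 9006 gene results stayed on their side of the threshold, with the same direction where called, 547 lost a call, 204 gained a call and 2 reversed. For lists the numbers were 1909, 51, 53 and 3. Direction was not compared for results called in neither setting. The 2-fold minimum, trend and robust eBayes, fits of 2 groups alone and the block keep the difference of a gene, so no gene could reverse there. Of counts, 119 stayed within 1.5 times and 36 did not, and of distances and correlations 47 moved by less than a spread and 13 by more. That spread was the SD over the 4 array pairs of 2 groups for a distance. For a correlation it was the SD of the values from replicate numbers 2 and 3. Where no reason is given below, the cause was not tested.

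Without the detection filter, which adds dim genes to the tests, the counts were 625 in Foxp3+RORgt- against Foxp3-RORgt- (main 946), 3940 in Foxp3-RORgt+ against Foxp3-RORgt- (2265), 479 in Foxp3+RORgt+ against Foxp3+RORgt- (817), 747 in Foxp3+RORgt+ against Foxp3-RORgt+ (1142), 6736 in Foxp3+RORgt+ against Foxp3-RORgt- (2340), 1173 in Foxp3+RORgt- against Foxp3-RORgt+ (1835) and 109 for the interaction (381). Foxp3-RORgt+ and Foxp3+RORgt+ against Foxp3-RORgt- then had mostly lower genes (2758 and 5351 lower, 1182 and 1385 higher). The shared Foxp3 and RORgt correlations were then 0.336 and 0.461. In Foxp3+RORgt+ against Foxp3-RORgt- cells, 4390 of 8490 dim genes were then lower and 30 higher (median of the lower ones -1.12). Negative control spots lay 1.11 higher on the Foxp3-RORgt- arrays (0.70 to 1.53 over 4 pairs of arrays), so a background that is higher against the 75th percentile could account for a shift of that size.

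Normexp gave 4219, 1794, 3775 and 2775 genes in Foxp3-RORgt+ against Foxp3-RORgt-, Foxp3+RORgt+ against Foxp3-RORgt+, Foxp3+RORgt+ against Foxp3-RORgt- and Foxp3+RORgt- against Foxp3-RORgt+. It gave distances of Foxp3+RORgt+ cells of 0.495 to Foxp3+RORgt- and 0.575 to Foxp3-RORgt+ cells, and a shared RORgt correlation of 0.577. In Foxp3+RORgt+ against Foxp3+RORgt- cells it reversed Blk (-0.0456, against 1.47 in the main setting) and Ptgdr2 (-0.0813, against 2.02). Median scaling gave 3442 genes in Foxp3-RORgt+ against Foxp3-RORgt- (3126 higher, 316 lower, against 1389 and 876) and 572 for the interaction (85 and 487, against 111 and 270). It split the calls of Foxp3+RORgt- and of Foxp3+RORgt+ against Foxp3-RORgt- into 1167 and 187 (main 659 and 287) and 2893 and 407 (1368 and 972), and those of Foxp3+RORgt+ against Foxp3+RORgt- into 492 and 247 (456 and 361). With unnamed features, which adds features, Foxp3-RORgt+ and Foxp3+RORgt+ against Foxp3-RORgt- gave 3456 (1553 higher, 1903 lower) and 3601 (1577 and 2024), and Foxp3+RORgt- against Foxp3-RORgt+ gave 1293 and 1024 (main 874 and 961). A fit of 2 groups alone, with fewer arrays, gave 1088 in Foxp3-RORgt+ against Foxp3-RORgt-. Detection on all 8 arrays, with fewer genes, gave 196 interaction genes, distances of 0.559 and 0.603 and a shared RORgt correlation of 0.588. It also turned the direction given by camera for 3 lists: CD8 T and NK cells in Foxp3+RORgt+ against Foxp3-RORgt+ (median -0.25), and NKT and gamma-delta T cells in Foxp3-RORgt+ against Foxp3-RORgt- (-0.43) and in the interaction (-0.16). In that setting the lists lack their members dim in a group, such as Ncr1 and Klrb1b.

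Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 423 to 1051, 1074 to 2067, 295 to 925, 505 to 1233, 1184 to 2218 and 857 to 2016 genes in the 6 comparisons, in the order Foxp3+RORgt- and Foxp3-RORgt+ against Foxp3-RORgt-, Foxp3+RORgt+ against Foxp3+RORgt-, Foxp3-RORgt+ and Foxp3-RORgt-, and Foxp3+RORgt- against Foxp3-RORgt+. The interaction ranged from 63 to 472 genes and the shared RORgt correlation from 0.459 to 0.501. With the replicate number as a block (replicate block) the counts were 1153, 2723, 955, 1335, 2746 and 2089 in the same order, and 495 for the interaction. Deviations of arrays with the same number correlated at 0.170 to 0.373, but the labels do not say what the numbers share. Signal over background limits the results too: 38.9% to 47.2% of probes were well above background, and genes dim in 1 group have only a lower bound.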

Other observations

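The lists below were fixed before the data were examined, no test in this part was chosen after its result was seen, and of the alternatives named only normexp on median signals was chosen after the files were seen. Plasma cell markers, 2 of which (Prdm1 and Irf4) are also in the effector Treg list, rose with RORgt. Of 5, 3 were higher in Foxp3-RORgt+ than in Foxp3-RORgt- cells (median 0.83), with Sdc1, a surface proteoglycan, at least 9.71-fold and Irf4 by 2.33 ± 0.18, and 3 were higher in Foxp3+RORgt+ than in Foxp3+RORgt- cells (median 1.59), with Sdc1 at least 3.05-fold and Prdm1 by 2.44 ± 0.23. The latter call of Sdc1 was lost with normexp in limma (adjusted p = 0.160). The list was called in both by camera in limma (adjusted p = 0.00766 and 0.000433), with adjusted p = 0.354 and adjusted p = 0.325 with an estimated correlation, and 4 and 3 members passed adjusted over the list alone. Without 1 array the former had as few as 2 members higher. In Foxp3+RORgt+ against Foxp3-RORgt+ cells, where the list was not called (adjusted p = 0.396), Prdm1 was higher by 2.40 ± 0.23 while Sdc1 differed by -2.66 ± 0.30. Markers of CD8 T and NK cells were called lower in 2 comparisons. In Foxp3+RORgt- against Foxp3-RORgt- cells 4 of 11 were lower (median -0.91, camera in limma adjusted p = 0.000250, and adjusted p = 0.382 with an estimated correlation), with Eomes at -2.47 ± 0.40, and 7 were lower and 1 higher adjusted over the list alone. Without either Foxp3+RORgt- replicate only 1 was lower. The call of Eomes was lost without Foxp3+RORgt- replicate 2 or 3 (limma adjusted p = 0.083 and 0.087). In Foxp3+RORgt+ against Foxp3-RORgt+ cells 3 were lower and 1 higher (median -0.52, adjusted p = 0.0245, and adjusted p = 0.641 with an estimated correlation), with Ncr1 at least 8.07-fold lower and the protease Gzmb higher by 3.69 ± 0.30. There, 5 were lower and 1 higher adjusted over the list alone, and the call was lost with normexp (adjusted p = 0.0968) and without Foxp3-RORgt+ replicate 3 (0.0705). Among members detected on all 8 arrays, which leave out Ncr1, it was lost as well (0.916, median -0.25), and the direction given by camera turned. Th1 genes, 2 of which are in the former list, fell in 3 of 14 and rose in 1 in Foxp3+RORgt- against Foxp3-RORgt- cells (median -0.92, adjusted p = 0.000381, and adjusted p = 0.542 with an estimated correlation), with Hopx higher by 1.83 ± 0.20. Adjusted p values over the list alone called 9 lower and 1 higher, and without Foxp3+RORgt- replicate 2 none was called lower at the main threshold. In Foxp3+RORgt+ against Foxp3+RORgt- cells 6 were lower and 2 higher (median -0.49, adjusted p = 0.0258, and adjusted p = 0.755 with an estimated correlation), and 6 and 3 adjusted over the list alone, with the chemokine Ccl5 at -3.40 ± 0.40 and Il18r1, a cytokine receptor chain, higher by 2.01 ± 0.19. That call was lost with normexp (0.0627), without the detection filter (0.169), among members detected on all 8 arrays (0.317) and without Foxp3+RORgt- replicate 3 (0.175), where 2 members were lower.

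In Foxp3-RORgt+ against Foxp3-RORgt- cells, interferon response genes fell in 5 of 20 and rose in 1, the same adjusted over the list alone (median -0.32, camera in limma adjusted p = 0.0333, and adjusted p = 0.759 with an estimated correlation), with Oas2 at -2.02 ± 0.20. The call was lost with normexp (0.129), without the detection filter (0.576), without Foxp3-RORgt- replicate 3 (0.139) and without Foxp3-RORgt+ replicate 2 (0.0533), where 1 member was lower. Glycolysis genes rose in 4 of 16 and fell in 1, with 5 and 1 adjusted over the list alone (median 0.32, adjusted p = 0.0479, and adjusted p = 0.755 with an estimated correlation). Hk2, a hexokinase, was at least 3.47-fold higher, and Pdk1 differed by -1.92 ± 0.26. This call was lost after scaling to the median (0.106), among members detected on all 8 arrays (0.0876), in a fit of the 2 groups alone (0.0507), and without Foxp3-RORgt- replicate 2 (0.0664) or 3 (0.0947), Foxp3-RORgt+ replicate 2 (0.141) or Foxp3+RORgt+ replicate 2 (0.0658) or 3 (0.0646). Myeloid and dendritic cell markers had 0 of 16 called in Foxp3+RORgt- against Foxp3-RORgt- cells, and 0 adjusted over the list alone (median -0.43, or -0.35 with 2 members at their bounds, camera in limma adjusted p = 0.0389, and adjusted p = 0.755 with an estimated correlation). Negative control spots lay at -5.33 in Foxp3+RORgt- and -4.65 in Foxp3-RORgt- cells, so background may add to this lower median. The list's call was lost after quantile normalization (0.104), without the detection filter (0.153), among members detected on all 8 arrays (0.0787), without Foxp3-RORgt- replicate 2 (0.121) or 3 (0.0523) and without Foxp3+RORgt- replicate 2 (0.229). Stromal and endothelial markers had 0 of 5 called in Foxp3+RORgt+ against Foxp3+RORgt- cells, and 1 lower adjusted over the list alone (median -0.43, or -0.62 over 4 members, adjusted p = 0.0359, and adjusted p = 0.382 with an estimated correlation). Their call was lost after quantile normalization (0.0776), without the detection filter (0.263), among members detected on all 8 arrays (0.123), without Foxp3+RORgt- replicate 3 (0.115) and without Foxp3+RORgt+ replicate 2 (0.0986). In Foxp3+RORgt+ against Foxp3-RORgt+ cells, proliferation genes had 1 of 27 lower and none higher, the same adjusted over the list alone (median -0.39, camera in limma adjusted p = 0.0134, and adjusted p = 0.755 with an estimated correlation). This call was lost without Foxp3-RORgt+ replicate 2 (0.371) and without Foxp3+RORgt+ replicate 3 (0.190). Genes low in Treg cells fell in 5 of 15 and rose in 1 in Foxp3-RORgt+ against Foxp3-RORgt- cells, with 7 and 1 adjusted over the list alone (median -0.63, adjusted p = 0.00115, and adjusted p = 0.485 with an estimated correlation), and the call was lost without the detection filter (0.0927). Without Foxp3-RORgt- replicate 2, 3 were lower and none higher. The Tfh and T cell identity lists were called in no comparison. Single Tfh genes were called, with 3 higher and 6 lower in Foxp3+RORgt+ than in Foxp3+RORgt- cells. Fewer were called higher without Foxp3+RORgt- replicate 3, and fewer lower without Foxp3+RORgt- replicate 2. Also not called in any comparison by camera in limma were Th2 genes (lowest adjusted p 0.0833, for the interaction), immediate early and heat shock genes (0.108, in Foxp3+RORgt- against Foxp3-RORgt- cells), cholesterol synthesis genes (0.132, in Foxp3+RORgt+ against Foxp3-RORgt+ cells), and erythroid and platelet markers (0.541, in Foxp3+RORgt- against Foxp3-RORgt- cells, with 2 members tested). Single members were called: Ccr4 was higher by 4.27 ± 0.27 in Foxp3-RORgt+ than in Foxp3-RORgt- cells, Nr4a1 by 1.15 ± 0.16 in Foxp3+RORgt- than in Foxp3-RORgt- cells, and Lss by 0.87 ± 0.16 in Foxp3-RORgt+ than in Foxp3-RORgt- cells. The call of Lss was lost in a fit of the 2 groups alone (limma adjusted p = 0.0538) and without Foxp3-RORgt+ replicate 2 (0.0709).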
